A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

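Total RNA from 15 yeast cultures was isolated with the RNeasy kit after mechanical disruption, checked on a Bioanalyzer, labelled with biotin and hybridised to Affymetrix yeast arrays, per the labels' protocols. The deposited values are on the log2 scale and were made by the authors with GCRMA, a background correction and summary of the probes of each probe set, per the submitters' processing notes, which give no version. The log2 scale was checked on the values themselves, which have a range typical of log2 intensities. No raw scanner files and no detection calls were used, so values near the low end of the scale are not marked as absent, and the number of arrays limits the precision.

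The value table held 5716 probe sets. Of these 5498 were paired with 1 yeast gene each by the platform annotation. The other 218 were not paired with exactly 1 gene and were left out of the gene tests. For 12 genes the symbol was updated through the Entrez identifier with the RefSeq gene table of assembly R64. Where a gene had several probe sets (47 genes), the one with the highest mean over all arrays was kept, which left 5449 genes. A further property of the array is that 132 of the 5716 probe sets carry the suffix by which Affymetrix marks sets that may match several transcripts. For 112 of the 5449 genes the probe set kept carries that suffix. Probe sets for human IRAK genes numbered 0.

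Arrays were grouped by the labels into Control (empty plasmid), IRAK4, IRAK4(KD), IRAK1 and IRAK2, with 3 biological replicates each. Values were used as deposited, with no further normalization and no filter. The 5 group means of all 15 arrays were fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with default settings), and 8 comparisons were made: each kinase against Control, IRAK4 against IRAK4(KD), and IRAK1 and IRAK2 against IRAK4 and IRAK2 against IRAK1. Tests were two-sided, p-values were adjusted over all genes by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05 with no limit on the fold change. Errors after ± are the standard errors of the limma contrasts unless SD is given. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

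The gene lists, comparisons, tests, thresholds, alternatives and the rule for named genes were chosen before the data were examined. There were 40 gene lists, written from general knowledge of yeast regulons and processes, and 39 with at least 5 measured members were tested with limma's camera (correlation between genes preset at 0.01, Benjamini-Hochberg over the 39 lists). Camera was also run with the correlation estimated for each list. For each list the members called over all genes and those called when adjusted over the list alone are given. Some genes belong to more than 1 list. The genes named are the 10 highest and 10 lowest fold changes among called genes whose arrays did not overlap between the groups, for the comparisons with Control and for IRAK4 against IRAK4(KD). For the other comparisons they are the 5 highest and 5 lowest of the same kind. Up to 3 called members of each list with the largest change were added, and GAL1, GAL2, GAL7, GAL10, GAL3, GAL80, URA3, LEU2, SLT2, FUS1, KAR2 and HSP12 were eligible whatever their values. A gene that this rule names in the comparisons of IRAK2 is not reported here.

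The alternatives were median centring and quantile normalization of the arrays, a filter on low values, the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, only the 6 arrays of the groups compared, a limit of 2-fold, the replicate number as a block, and each array left out in turn. A fit without IRAK1 replicate 1 for all groups, and the replicate block in the 6 arrays of IRAK1 and Control, were added after the data were seen. No label says what a replicate number stands for. Pairing was checked by correlating the deviations of same-numbered arrays from their group means across genes. In IRAK1 and Control these were 0.19, 0.10 and 0.35 for numbers 1, 2 and 3, so that by the rule applied here (every pair over 0.1 before rounding) the numbers pair these arrays, and the source of the pairing is unknown. The block gave 3157 genes for IRAK1 against Control in place of 3201, and 2520 in place of 2455 with the 6 arrays alone.

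The procedure was tested on simulated data for 5449 genes, a random set of them changed. Each gene had its mean over all arrays and its pooled spread, the same in every group. Every comparison was drawn a single time, so differences between comparisons in the values below come from the random draw. The larger spread of the IRAK1 arrays was not simulated. For IRAK4 against Control limma recovered 67.2% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and 100% of changes of 2, and 2.75% of its calls were false. For IRAK2 against Control these were 68.7%, 97.0%, 100% and 2.21%, the lowest share of false calls among the 8 comparisons. The highest was 5.24%, for IRAK1 against Control, and the lowest recovery of changes of 1 was 92.5%, for IRAK2 against IRAK4, where 4.89% of calls were false.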

Results

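Messenger RNA was measured in budding yeast (Saccharomyces cerevisiae, laboratory strain YPH499) that carried human kinases of the interleukin-1 receptor-associated kinase (IRAK) family, proteins that act below Toll-like and interleukin-1 receptors in human immune cells. The cells held the plasmid pEG(KG), in which the galactose-inducible GAL1 promoter drove IRAK4, a catalytically inactive form of IRAK4 called IRAK4(KD), IRAK1 or IRAK2, and the empty plasmid served as Control. Cultures grew for 18 h in raffinose medium, were diluted to an optical density of 0.3 and spent 6 h in galactose medium, both at 30 °C. Each of the 5 groups had 3 biological replicates on 1 Affymetrix array each, 15 arrays in all, and 5449 yeast genes were tested. The median log2 value of an array over these genes lay between 8.72 and 8.87. Correlations across genes between replicate arrays were at least 0.993 in Control, IRAK4, IRAK4(KD) and IRAK2. In IRAK1 they went down to 0.968, because replicate 1 correlated at 0.968 with both other IRAK1 arrays, which correlated with each other at 0.994. IRAK1 replicate 1 differed by more than 1 log2 unit from the mean of the other 2 IRAK1 arrays in 234 genes, and it entered all comparisons. Changes are given as log2 differences ± the standard error from limma, with 3 arrays per group. That error uses 1 spread per gene, estimated from all 15 arrays, so IRAK1 replicate 1 also enters it in comparisons without IRAK1. A gene is said to rise, fall or be called only where the Benjamini-Hochberg adjusted p of limma was under 0.05. The arrays held no probe set for a human IRAK gene, so the level of the introduced kinases was not measured here.

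The galactose genes report on the induction itself. GAL1, which encodes galactokinase, had a log2 value of 13.40 ± 0.03 (SD, n = 3) in Control, where the highest value of an array was 13.96 to 14.04. Its differences from Control were 0.04 ± 0.07 in IRAK4, 0.06 ± 0.07 in IRAK4(KD), 0.08 ± 0.07 in IRAK1 and -0.17 ± 0.07 in IRAK2, none of them called. GAL10, which encodes the epimerase of the same pathway, and GAL80, its repressor, were not called in any of the 4 comparisons with Control. With array weights GAL1 (-0.22), GAL10 (-0.18) and GAL80 (-0.25) were called lower in IRAK2, GAL80 also from the 6 arrays alone or without IRAK1 replicate 1 (-0.25 in both). After quantile normalization GAL10 was called higher in IRAK1 (0.20). GAL2, the galactose permease, rose by 0.27 ± 0.08 in IRAK4, 0.39 ± 0.08 in IRAK4(KD) and 0.52 ± 0.08 in IRAK1. Its call ended in IRAK4 without Control replicate 3 (0.20) or IRAK4 replicate 3 (0.23) and in IRAK4(KD) without Control replicate 3 (0.32). GAL7 rose by 0.33 ± 0.06, 0.29 ± 0.06 and 0.25 ± 0.06 in these groups. Its call in IRAK4(KD) ended without Control replicate 3 (0.26), and that in IRAK1 in a fit of the 6 arrays alone (0.25). GAL3, the galactose sensor, fell in IRAK1 (-0.31 ± 0.13), a call that each single removal of a Control array or of IRAK1 replicate 2 or 3 ended (-0.19 to -0.35). For GAL3, IRAK1 vs Control was at -0.50 without IRAK1 replicate 1. Of the 10 measured genes of the galactose list, 4 rose and 1 fell in IRAK4, 4 rose in IRAK4(KD) (2 without Control replicate 3), 5 rose and 2 fell in IRAK1 and 0 were called in IRAK2, where 5 were lower when adjusted over the list alone and 4 without IRAK1 replicate 1. The differences of the list's members ran from -0.42 to 0.86 in IRAK4, -0.23 to 0.58 in IRAK4(KD), -1.18 to 1.02 in IRAK1 and -0.43 to 0.11 in IRAK2. The list's median difference was 0.02 in IRAK4, which turned to -0.05 with each array centred on its median, 0.19 in IRAK4(KD), 0.19 in IRAK1 and -0.19 in IRAK2. The camera test called the list in IRAK2 (lower, adjusted p = 0.0014) and in none of the others. That call was lost with an estimated correlation (adjusted p = 0.26 with an estimated correlation).

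**Figure D1:**
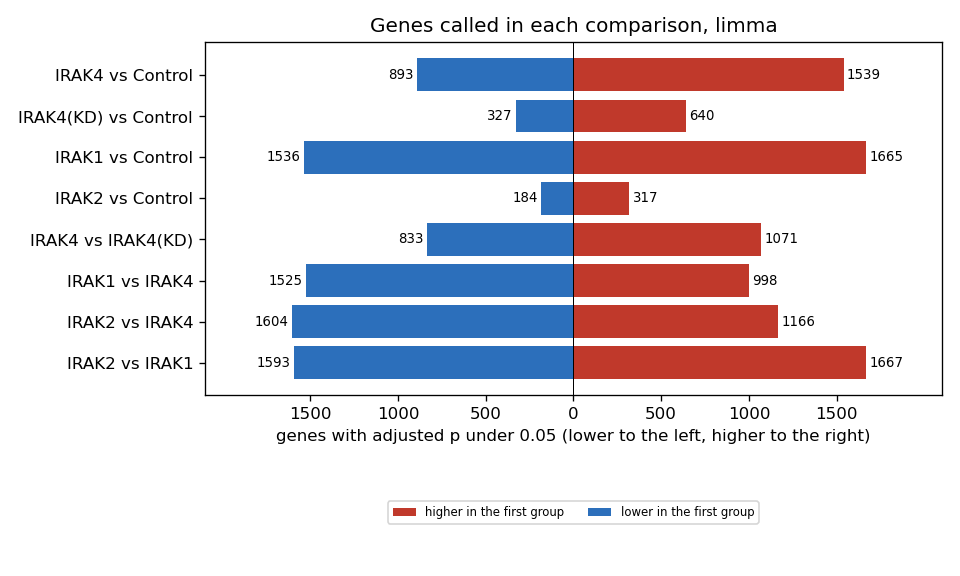
Number of genes called by limma in each comparison, of 5449 tested. Bars to the right count genes higher in the first group of the comparison and bars to the left genes lower in it. IRAK1 differed from Control in 1665 genes that were higher and 1536 that were lower, IRAK2 in 317 and 184.

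The comparison of IRAK4 with Control asked which yeast genes respond to the active human kinase. The genes of the environmental stress response that the transcription factors Msn2 and Msn4 control were higher in IRAK4 in 45 of 48 measured members, and 0 fell. CTT1 (YGR088W), the cytosolic catalase, went from a log2 value of 8.98 ± 0.11 (SD, n = 3) to 3.56 ± 0.15 above it, about 12-fold (adjusted p = 1.76e-09). TKL2, a transketolase, rose by 3.49 ± 0.22, GRE1, a stress-induced hydrophilin, by 3.85 ± 0.64 and GND2, a phosphogluconate dehydrogenase, by 3.20 ± 0.32. GRE1 read 12.20 to 12.28 in IRAK4 and 7.91 to 8.68 in Control. Its error also holds the wider spread of the IRAK1 arrays, 9.31 to 12.93. RTN2, a reticulon, rose by 3.05 ± 0.22 and ALD3, an aldehyde dehydrogenase, by 3.00 ± 0.27. Outside this list FMP48 (YGR052W), a putative kinase, rose by 3.62 ± 0.16 and FMP45, an eisosome protein, by 3.03 ± 0.16. HSP12, whose log2 value in Control was already 13.59, rose by 0.29 ± 0.07. Of the stress list 46 members were higher when adjusted over the list alone, and the median difference was 1.13. The camera test called it (adjusted p = 1.20e-22), a call lost with an estimated correlation between genes (adjusted p = 0.0743 with an estimated correlation).

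Genes for the use of non-fermentable carbon were lower in IRAK4. Of 23 genes of gluconeogenesis and the glyoxylate cycle 17 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.96. ADH2 (YMR303C), the alcohol dehydrogenase that consumes ethanol, fell by 3.01 ± 0.12 from a log2 value of 13.49 ± 0.18 (SD, n = 3) in Control. ADY2, the acetate transporter, stood at -2.66 ± 0.20 and ICL2, a mitochondrial 2-methylisocitrate lyase, at -2.48 ± 0.34. Of 27 genes of fatty acid oxidation and peroxisomes 17 fell and 1 rose (the same numbers adjusted over the list alone), among them the peroxisomal catalase CTA1 (-2.28 ± 0.18) and the acyl-CoA oxidase POX1 (-2.09 ± 0.21). Of 19 glycolysis genes 15 rose and 1 fell, also when adjusted over the list alone, with TDH1 at 1.52 ± 0.25 and ENO1 at 1.30 ± 0.15 above Control and the hexokinase gene HXK2 at -1.04 ± 0.14. The camera test called all 3 lists (adjusted p = 1.52e-11, 3.92e-07 and 3.83e-04). Each call was lost with an estimated correlation (adjusted p = 0.25, 0.54 and 0.24 with an estimated correlation). HXT2, a high-affinity glucose transporter, fell by 3.01 ± 0.29, and the sulfate permease SUL1 (YBR294W) had the largest fall of all genes called, -3.29 ± 0.24. In IRAK4 the values of SUL1 (4.12 to 4.43) lay near the low end of the arrays, so the size of its fall is uncertain. FDH1, formate dehydrogenase, fell by 2.46 ± 0.33 and the cell wall mannoprotein TIP1 by 2.33 ± 0.11.

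Other groups also moved in IRAK4. Of 40 proteasome genes 30 rose and 1 fell (31 and 2 adjusted over the list alone, median 0.33). Of 29 genes of autophagy and vacuolar proteolysis 17 rose and 1 fell (18 and 1 adjusted over the list alone, median 0.53), including ATG8 at 1.18 ± 0.14. In the cell wall integrity list 16 of 31 genes rose and 2 fell (17 and 2 adjusted over the list alone, median 0.28). SLT2, the MAP kinase of that pathway, rose by 0.47 ± 0.10. Of 17 genes of the osmotic stress (Hog1) list 12 rose and 1 fell (13 and 2 adjusted over the list alone, median 0.73). As written, that list shares CTT1, GRE1, HSP12, PAI3, RTC3 and TSL1 with the Msn2/Msn4 list. Of 29 iron regulon genes 17 fell and 1 rose (18 and 1 adjusted over the list alone), with FIT3, a cell wall mannoprotein for siderophore retention, at -2.35 ± 0.32. Of 128 ribosomal protein genes 58 fell and 1 rose, also when adjusted over the list alone, with a median of -0.26, and 90 fell without IRAK1 replicate 1. The camera test called these 6 lists (adjusted p = 1.04e-04, 8.08e-05, 0.0177, 1.54e-04, 4.15e-08 and 1.29e-14). None of the calls was kept (adjusted p = 0.44, 0.0743, 0.60, 0.0930, 0.25 and 0.49 with an estimated correlation).

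In all, limma called 2432 of 5449 genes in IRAK4 against Control, 1539 higher and 893 lower, of which 177 and 107 changed at least 2-fold. The values of the 3 IRAK4 arrays lay wholly above or below those of the 3 Control arrays in 61.7% of all genes, where chance gives 10%. The share of higher genes among those called depended on scaling: it was 63.3% as deposited, 52.4% (1285 higher, 1166 lower) with each array centred on its median and 51.0% (1222 higher, 1173 lower) after quantile normalization.

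**Figure D2:**
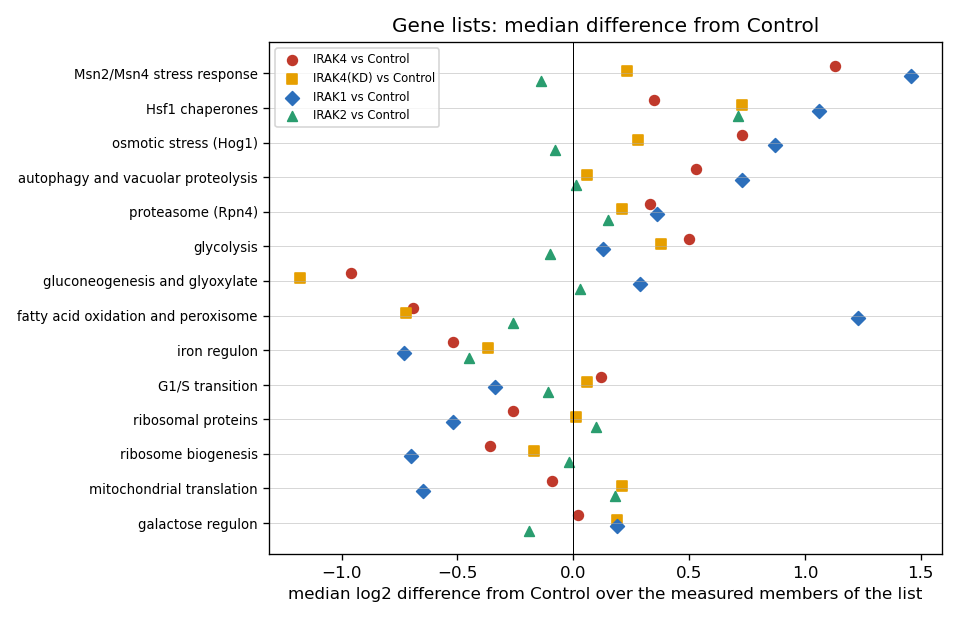
Median log2 difference from Control over the measured members of 14 gene lists, for each of the 4 kinase groups (points, 3 arrays per group; no error is drawn). The Msn2/Msn4 list lies at 1.13 in IRAK4 and 1.46 in IRAK1, at 0.23 in IRAK4(KD) and -0.14 in IRAK2, while the Hsf1 list lies at 0.35 or above in every group.

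The comparison of the inactive kinase with Control asked which changes come without catalytic activity of IRAK4. The chaperone genes controlled by the heat shock factor Hsf1 rose in IRAK4(KD) in 29 of 30 members, also when adjusted over the list alone, with a median of 0.73. BTN2, a protein sorting factor for misfolded proteins, rose by 1.61 ± 0.18, and the Hsp70 genes SSA4 and SSA3 by 1.46 ± 0.11 and 1.35 ± 0.30. The small heat shock protein gene HSP26, of the Msn2/Msn4 list, rose by 1.56 ± 0.23. The Hsf1 list was the 1 list whose camera call (adjusted p = 1.20e-21) was kept, with adjusted p = 0.0277 with an estimated correlation. KAR2, the Hsp70 of the endoplasmic reticulum, rose by 0.72 ± 0.11. In the same group 7 of 30 genes of the unfolded protein response list rose and 0 fell (9 and 0 adjusted over the list alone). The number that rose was 3 without Control replicate 2, 2 without Control replicate 3, and 4 and 3 without IRAK4(KD) replicate 2 and 3. Camera did not call that list (adjusted p = 0.0714).

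Genes of the same carbon lists fell in IRAK4(KD). Of the 23 genes of gluconeogenesis and the glyoxylate cycle 19 fell (19 lower and 1 higher adjusted over the list alone, median -1.18), with ADY2 at -2.38 ± 0.20, the malate synthase MLS1 at -1.85 ± 0.09 and ICL2 at -1.74 ± 0.34. Of the 27 fatty acid oxidation and peroxisome genes 17 fell and 1 rose (19 and 1 adjusted over the list alone, median -0.72), with CTA1 at -1.82 ± 0.18. Of 19 glycolysis genes 12 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.38). The camera calls of these 3 lists (adjusted p = 9.83e-23, 1.49e-13 and 5.43e-06) were lost with an estimated correlation (adjusted p = 0.0746, 0.33 and 0.0746 with an estimated correlation). SUL1 fell by 3.87 ± 0.24 and HXT2 by 2.36 ± 0.29. In IRAK4(KD) the values of SUL1 (3.59 to 3.88) lay near the low end of the arrays, so the size of its fall is uncertain. MIG2, a repressor of glucose-repressed genes, fell by 2.04 ± 0.24, and GAP1, the general amino acid permease, by 1.51 ± 0.16.

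The highest rises in IRAK4(KD) were in YOR387C (3.53 ± 0.27), a gene of unknown function, VEL1 (2.80 ± 0.33) and ZPS1 (2.03 ± 0.16), a cell surface protein induced at low zinc. YOR387C had log2 values near the low end of the array in Control (4.58 ± 0.23, SD, n = 3), as did VEL1 (3.21 ± 0.34, SD, n = 3). Of 16 zinc regulon genes 3 rose and 0 fell, ZPS1, ADH4 (1.34 ± 0.12) and MCD4 (0.44 ± 0.10). Without IRAK1 replicate 1, 7 rose and 1 fell. When adjusted over the list alone 6 rose, with a median of 0.31 (camera, adjusted p = 0.0102; adjusted p = 0.42 with an estimated correlation). The call of MCD4 ended without Control replicate 3 (0.39) or IRAK4(KD) replicate 2 (0.38). SPI1, a cell wall protein, rose by 1.69 ± 0.16 and CHA1, serine and threonine deaminase, by 1.66 ± 0.36. Of the 48 Msn2/Msn4 genes 14 rose and 2 fell, also when adjusted over the list alone, with a median of 0.23 (camera, adjusted p = 0.00107; adjusted p = 0.52 with an estimated correlation), and 9 rose without Control replicate 3 and 22 without IRAK1 replicate 1. Of 29 iron regulon genes 14 fell and 1 rose (17 and 1 adjusted over the list alone; camera, adjusted p = 4.42e-10; adjusted p = 0.13 with an estimated correlation), and 8 fell without Control replicate 2, Control replicate 3 or IRAK4(KD) replicate 1.

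In all, 967 genes were called in IRAK4(KD) against Control, 640 higher and 327 lower, with 25 and 61 at least 2-fold, and 48.5% of all genes showed no overlap between the 6 arrays (10% by chance). This count fell to 438 without Control replicate 2, 325 without Control replicate 3, 527 without IRAK4(KD) replicate 1 and 446 without IRAK4(KD) replicate 2. It rose to 1857, including all 967, when IRAK1 replicate 1 was left out of the shared estimate of the spread. The share of higher genes among those called was 66.2% as deposited, 55.9% (538 higher, 424 lower) with median centring and 54.7% (495 higher, 410 lower) after quantile normalization.

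**Figure D3:**
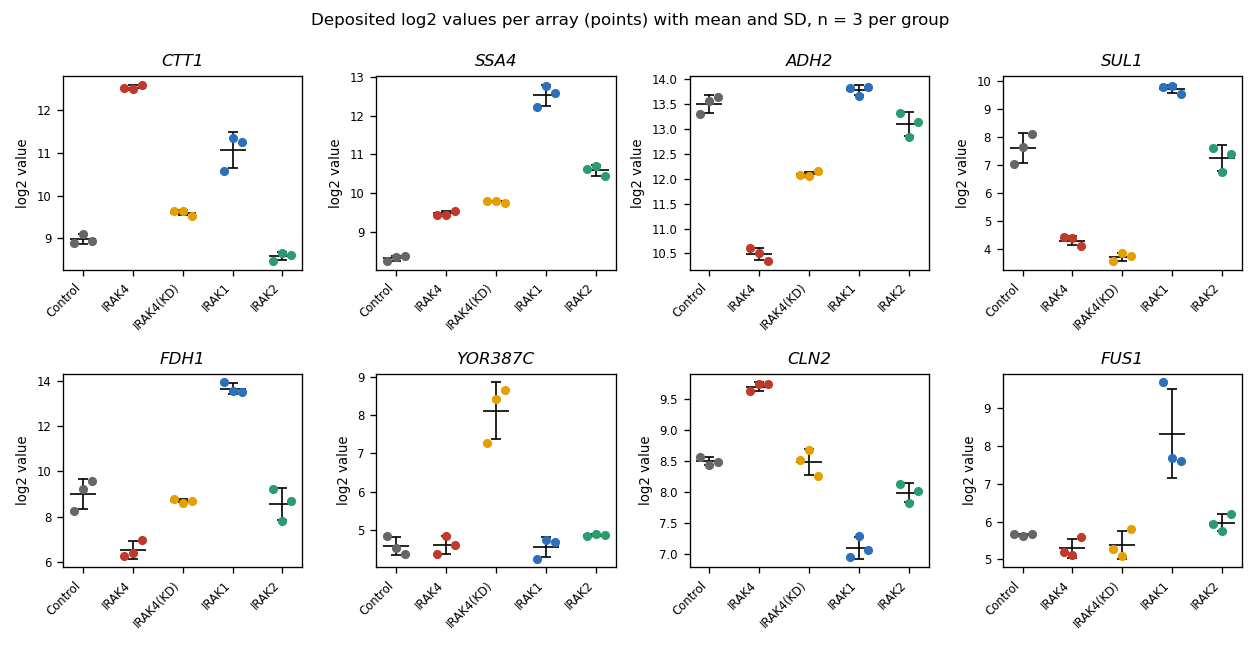
Deposited log2 values of 8 named genes on each of the 15 arrays (points, vertical axes in log2 units that do not start at 0), with the mean and SD of the 3 arrays of each group. CTT1 lies highest in IRAK4, SSA4 and FDH1 in IRAK1, and YOR387C in IRAK4(KD); FUS1 lies at 9.68 on IRAK1 replicate 1 and at 7.69 and 7.61 on the other IRAK1 arrays.

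IRAK4 and IRAK4(KD), which differ in catalytic activity, were also compared directly. The Msn2/Msn4 genes were higher in IRAK4 in 41 of 48 members and lower in 3 (43 and 4 adjusted over the list alone), with a median of 1.01. Among the members GRE1 was 3.36 ± 0.64 higher in IRAK4, TKL2 3.09 ± 0.22, CTT1 2.95 ± 0.15 and PHM7 2.60 ± 0.23. Outside the list FMP48 was 3.52 ± 0.16 higher, HBT1, a protein of the mating projection, 2.77 ± 0.21 and PMA2, a plasma membrane proton pump, 2.60 ± 0.28. Of the 17 osmotic stress genes, some of which (CTT1 and GRE1 among them) are also on the Msn2/Msn4 list, 12 were higher and 0 lower, also when adjusted over the list alone. Of the 29 autophagy and vacuolar proteolysis genes 18 were higher and 1 lower (21 and 2 adjusted over the list alone). Camera called these lists (adjusted p = 4.52e-20, 6.85e-05 and 2.41e-06), and the calls were lost with an estimated correlation (adjusted p = 0.0643, 0.0643 and 0.0503 with an estimated correlation).

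The Hsf1 chaperones went the other way: 19 of 30 were lower in IRAK4 than in IRAK4(KD) and 3 were higher (23 and 4 adjusted over the list alone, median -0.45; camera, adjusted p = 1.44e-07; adjusted p = 0.20 with an estimated correlation). Against Control 17 of them rose in IRAK4 and 6 fell, also when adjusted over the list alone, with a median of 0.35, and camera did not call the list (adjusted p = 0.119). The number higher than in IRAK4(KD) was 1 without IRAK4 replicate 2 or 3 and 0 without IRAK4(KD) replicate 2 or 3. The Hsp70 gene SSA2 differed by -1.58 ± 0.07, BTN2 by -1.48 ± 0.18 and KAR2, outside the list, by -0.73 ± 0.11. YOR387C (-3.51 ± 0.27), invertase SUC2 (-3.01 ± 0.11), VEL1 (-2.55 ± 0.33), ZPS1 (-2.51 ± 0.16), TIP1 (-2.29 ± 0.11) and the inositol phosphate synthase INO1 (-2.17 ± 0.27) were the most lowered in IRAK4. In IRAK4 the values of YOR387C (4.38 to 4.83) and VEL1 (3.28 to 3.72) lay near the low end of the arrays. The size of their differences is therefore uncertain. Of the 128 ribosomal protein genes 62 were lower in IRAK4 and 0 higher (75 and 0 adjusted over the list alone, median -0.27; camera, adjusted p = 5.99e-15; adjusted p = 0.53 with an estimated correlation). That number was 40 without IRAK4 replicate 1, 33 without IRAK4(KD) replicate 2, 41 without IRAK4(KD) replicate 3, 35 after quantile normalization and 94 without IRAK1 replicate 1. Of the gluconeogenesis and glyoxylate genes 5 were higher and 5 lower, also when adjusted over the list alone (8 and 8 without IRAK1 replicate 1; 3 lower with IRAK4 replicate 1 or 2 or any 1 IRAK4(KD) array left out), and camera did not call that list (adjusted p = 0.99). In all 1904 genes were called, 1071 higher and 833 lower in IRAK4, with 143 and 45 at least 2-fold, and 52.4% of genes showed no overlap (10% by chance). The numbers were 1021 higher and 1002 lower with median centring, 985 and 975 after quantile normalization and 1370 and 1520 with array weights.

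**Figure D4:**
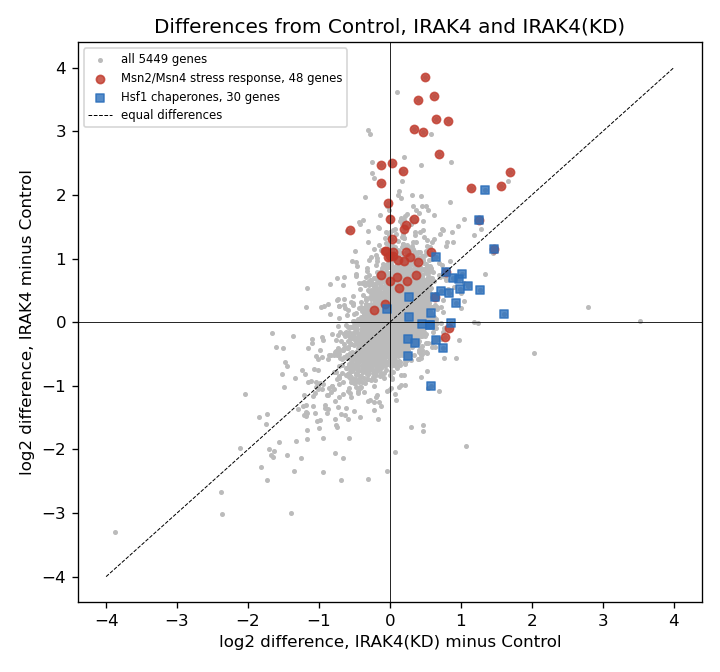
Log2 difference from Control in IRAK4 (vertical) against that in IRAK4(KD) (horizontal) for 5449 genes, with the 48 Msn2/Msn4 genes and the 30 Hsf1 genes marked and a dashed line where both differences are equal; the 2 lists share some genes and both axes use the same Control arrays. Most Msn2/Msn4 genes lie above the line, 41 of them with a called difference, and most Hsf1 genes to the right of the vertical zero line, 29 of them with a called rise in IRAK4(KD).

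The comparison of IRAK1 with Control includes the deviating replicate 1 in all of its values. All 48 Msn2/Msn4 genes rose, also when adjusted over the list alone and without replicate 1, with a median of 1.46. SSA4 (YER103W), which is also on the Hsf1 list, had a difference of 4.21 ± 0.11 (adjusted p = 7.03e-12), TKL2 of 3.88 ± 0.22 and GRE1 of 3.18 ± 0.64. GRE1 stood at 9.31 on replicate 1 and at a mean of 12.68 on the other 2 arrays, and its difference was 4.30 without replicate 1 and 2.49 without replicate 2. Of the 30 Hsf1 chaperones 26 rose and 0 fell, also when adjusted over the list alone, with a median of 1.06, and KAR2 rose by 0.99 ± 0.11. The autophagy and vacuolar proteolysis list had 25 of 29 genes higher and 1 lower (26 and 1 adjusted over the list alone, median 0.73), with ATG34 at 1.79 ± 0.12. It was the 1 list whose camera call was kept (adjusted p = 1.62e-08; adjusted p = 0.0173 with an estimated correlation). The calls of the Msn2/Msn4 list (adjusted p = 1.19e-21) and the Hsf1 list (adjusted p = 1.65e-12) were lost (adjusted p = 0.0543 and 0.0650 with an estimated correlation).

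Genes of fatty acid oxidation and peroxisomes rose in IRAK1, with 23 of 27 higher and 1 lower (24 and 1 adjusted over the list alone, median 1.23; camera, adjusted p = 1.50e-08; adjusted p = 0.36 with an estimated correlation). DCI1, a peroxisomal isomerase of that pathway, rose by 3.06 ± 0.28 and PEX18, an import receptor, by 2.63 ± 0.13. Lists of mitochondrial respiration, which share some genes, went the other way. Without replicate 1, 3 genes of the mitochondrial respiratory chain rose and 35 fell (median -0.60). In the same fit 1 gene of the tricarboxylic acid (TCA) cycle rose and 13 fell (median -0.51). Formate dehydrogenase FDH1 (YOR388C) had the largest rise, 4.64 ± 0.33 from 9.02 ± 0.68 (SD, n = 3) in Control. DDI3, read by a probe set that may match several transcripts, rose by 4.38 ± 0.25, SPG1, a gene needed in stationary phase, by 3.74 ± 0.18 and CHA1 by 3.53 ± 0.36 (4.18 without replicate 1). FUS1, a gene of mating cell fusion, rose by 2.67 ± 0.39, with 9.68 on replicate 1 and 7.69 and 7.61 on replicates 2 and 3. For FUS1, IRAK1 vs Control was at 1.99 without replicate 1. Of 26 pheromone response genes 7 rose and 6 fell, also when adjusted over the list alone, and 4 rose without Control replicate 3 or IRAK1 replicate 2. Camera did not call the list (adjusted p = 0.77). Of 30 genes of meiosis and sporulation 15 rose and 6 fell, also when adjusted over the list alone (camera, adjusted p = 0.0110; adjusted p = 0.40 with an estimated correlation). Without Control replicate 3 or IRAK1 replicate 3 the number that fell was 3. The meiotic recombinase DMC1 stood at 3.56 ± 0.20 and SPO1 at 2.31 ± 0.08.

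Genes of protein synthesis were lower in IRAK1. Of 128 ribosomal protein genes 122 fell and 1 rose (124 and 1 adjusted over the list alone, median -0.52). Of 91 ribosome biogenesis genes 83 fell and 0 rose (86 and 0 adjusted over the list alone, median -0.70). Of 64 genes of mitochondrial translation 62 fell and 0 rose, also when adjusted over the list alone (median -0.65). Without replicate 1 the numbers that fell were 120, 71 and 62, with medians of -0.44, -0.40 and -0.66. The camera calls (adjusted p = 4.39e-21, 1.65e-12 and 1.47e-17) were lost (adjusted p = 0.28, 0.51 and 0.0837 with an estimated correlation). Of 35 genes of the G1/S transition 19 fell and 1 rose, also when adjusted over the list alone (camera, adjusted p = 5.25e-05; adjusted p = 0.0780 with an estimated correlation). Among them were the cohesin subunit MCD1 (-1.61 ± 0.09), the ribonucleotide reductase RNR1 (-1.52 ± 0.12) and the G1 cyclin CLN2 (-1.40 ± 0.12). The S-adenosylmethionine synthetases SAM1 and SAM2 fell by 2.45 ± 0.11 and 2.04 ± 0.15, and the mating-type endonuclease HO by 2.87 ± 0.18. Of 29 iron regulon genes 20 fell and 5 rose (21 and 5 adjusted over the list alone; camera, adjusted p = 2.67e-04; adjusted p = 0.36 with an estimated correlation). The multicopper oxidase FET3 stood at -2.83 ± 0.28 and the ferric reductase FRE4 at 2.53 ± 0.10. In all 3201 genes were called, 1665 higher and 1536 lower (1593 higher and 1697 lower with median centring, 1485 and 1792 after quantile normalization), with 358 and 139 at least 2-fold, and 60.4% of genes showed no overlap (10% by chance). Of the iron genes 3 rose without Control replicate 1, Control replicate 3 or IRAK1 replicate 1. Without IRAK1 replicate 1 the count of all genes was 3318, of which 2922 were among the 3201.

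IRAK2 changed fewer genes against Control, and the chaperones of the Hsf1 list stood out among them. Of the 30 Hsf1 genes 26 rose and 0 fell, also when adjusted over the list alone, with a median of 0.71. SSA4 rose by 2.27 ± 0.11 (adjusted p = 3.99e-08), BTN2 by 1.96 ± 0.18, CUR1, a sorting factor related to BTN2, by 1.57 ± 0.12 and HSP82, an Hsp90, by 1.12 ± 0.13. This list kept its camera call (adjusted p = 8.39e-31; adjusted p = 0.00680 with an estimated correlation). KAR2 rose by 0.67 ± 0.11, and of 30 unfolded protein response genes 4 rose and 1 fell, also when adjusted over the list alone (camera, adjusted p = 0.92). Of these, 1 rose without Control replicate 2 or IRAK2 replicate 3 and 2 without Control replicate 3. MBF1, a transcriptional coactivator, rose by 1.00 ± 0.10, YDR222W by 1.20 ± 0.24 and the hexose transporter gene HXT11 by 1.29 ± 0.19 from a Control value of 3.08 ± 0.13 (SD, n = 3) near the low end of the array. PHD1, a regulator of filamentous growth, fell by 1.21 ± 0.13 and GTO3, a glutathione transferase, by 1.03 ± 0.16.

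Of the 48 Msn2/Msn4 genes 5 rose and 12 fell in IRAK2 (5 and 17 adjusted over the list alone, median -0.14; camera, adjusted p = 0.0278; adjusted p = 0.68 with an estimated correlation). The number that fell was 3 without Control replicate 2, 7 without Control replicate 3 or IRAK2 replicate 1, and 4 without IRAK2 replicate 2 or 3. Without IRAK1 replicate 1, 8 rose and 19 fell. Of 29 iron regulon genes 14 fell and 0 rose (18 and 1 adjusted over the list alone, median -0.45; camera, adjusted p = 2.94e-10; adjusted p = 0.26 with an estimated correlation). That number was 9, 2 and 7 without Control replicate 1, 2 and 3, and 7, 8 and 3 without IRAK2 replicate 1, 2 and 3, and it was 21 without IRAK1 replicate 1. Of 128 ribosomal protein genes 4 rose and 0 fell (1 and 0 adjusted over the list alone; camera, adjusted p = 0.0174; adjusted p = 0.86 with an estimated correlation). At most 2 rose with any 1 of the 6 arrays left out, and 13 rose and 1 fell without IRAK1 replicate 1. Of 23 gluconeogenesis and glyoxylate genes 3 rose and 0 fell (4 and 1 adjusted over the list alone; camera, adjusted p = 0.74), and 5 rose and 1 fell without IRAK1 replicate 1. In all 501 genes were called, 317 higher and 184 lower, with 7 and 6 at least 2-fold, and 42.8% of genes showed no overlap (10% by chance). The count was 177 without Control replicate 2, 222 without Control replicate 3, 300, 285 and 146 without IRAK2 replicate 1, 2 and 3, and 1180, including all 501, when IRAK1 replicate 1 was left out of the estimate of the spread.

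The kinases were also compared with each other. IRAK1 differed from IRAK4 in carbon genes, and 24 of 27 fatty acid oxidation and peroxisome genes were higher in IRAK1 and 0 lower, also when adjusted over the list alone (median 1.85; camera, adjusted p = 2.26e-19; adjusted p = 0.23 with an estimated correlation). FDH1 was 7.10 ± 0.33 higher, ADY2 5.24 ± 0.20 and CTA1 4.39 ± 0.18. Not all carbon lists were higher in IRAK1. Without IRAK1 replicate 1, 3 genes of the mitochondrial respiratory chain were higher and 36 lower (median -0.73). In the same fit 2 genes of the TCA cycle were higher and 14 lower (median -0.73). Of 23 gluconeogenesis and glyoxylate genes 15 were higher and 2 lower, also when adjusted over the list alone (camera, adjusted p = 1.05e-08; adjusted p = 0.30 with an estimated correlation). Of 35 G1/S genes 22 were lower in IRAK1 and 0 higher, also when adjusted over the list alone (median -0.70; camera, adjusted p = 2.20e-07; adjusted p = 0.0523 with an estimated correlation), CLN2 among them at -2.61 ± 0.12. The Hsf1 list had 24 of 30 genes higher in IRAK1 and 0 lower, also when adjusted over the list alone (camera, adjusted p = 8.43e-15; adjusted p = 0.0523 with an estimated correlation). In all 2523 genes were called, 998 higher and 1525 lower in IRAK1, with 220 and 112 at least 2-fold, and 46.3% showed no overlap (10% by chance).

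IRAK2 had lower stress genes than IRAK4, with 42 of 48 Msn2/Msn4 genes lower and 2 higher, also when adjusted over the list alone (median -1.58; camera, adjusted p = 1.51e-17; adjusted p = 0.0832 with an estimated correlation). GRE1 stood at -4.02 ± 0.64, CTT1 at -3.96 ± 0.15 and FMP48, outside the list, at -3.80 ± 0.16. Of 23 gluconeogenesis and glyoxylate genes 18 were higher in IRAK2 and 0 lower (18 and 1 adjusted over the list alone; camera, adjusted p = 2.75e-09; adjusted p = 0.30 with an estimated correlation). SUL1 was 2.94 ± 0.24 and ADH2 2.60 ± 0.12 higher. The size of the SUL1 difference is uncertain, as its IRAK4 values (4.12 to 4.43) lay near the low end of the arrays. Here 2770 genes were called, 1166 higher and 1604 lower in IRAK2 (1424 higher and 1397 lower after quantile normalization), with 138 and 230 at least 2-fold, and 65.4% showed no overlap (10% by chance). Against IRAK1, IRAK2 had 47 of 48 Msn2/Msn4 genes lower and 0 higher (median -1.71; camera, adjusted p = 2.54e-22; adjusted p = 0.0514 with an estimated correlation). It had 123 of 128 ribosomal protein genes higher and 0 lower (median 0.62; camera, adjusted p = 2.54e-22; adjusted p = 0.30 with an estimated correlation), and both numbers were the same when adjusted over the list alone. The autophagy and vacuolar proteolysis list, with 24 of 29 lower and 1 higher, also when adjusted over the list alone, kept its camera call (adjusted p = 1.68e-08; adjusted p = 0.0168 with an estimated correlation). FDH1 was at -5.08 ± 0.33 and TKL2 at -4.07 ± 0.22, while HO was 2.33 ± 0.18 and SAM1 2.23 ± 0.11 higher in IRAK2. In all 3260 genes were called, 1667 higher and 1593 lower in IRAK2, with 176 and 385 at least 2-fold, and 62.0% showed no overlap (10% by chance).

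Calls were shared between constructs. IRAK4 and IRAK4(KD) shared 347 genes higher and 207 lower than Control, where independent lists would share 181 and 54, and 55 genes went in opposite directions. IRAK4 and IRAK1 shared 932 higher and 530 lower (470 and 252 for independent lists), with 230 opposite. IRAK4 and IRAK2 shared 88 higher and 51 lower (89.5 and 30.2), with 157 opposite, and IRAK1 and IRAK2 shared 141 higher and 64 lower (96.9 and 51.9), with 146 opposite. Without IRAK1 replicate 1 the numbers in opposite directions were 163, 363, 430 and 327. The numbers in opposite directions were not set against those of independent lists. All pairs used the same 3 Control arrays. In 100 simulations all arrays, the controls among them, were redrawn with no group changed, and each pair shared its simulated controls. The mean number of shared calls was at most 0.03, and the correlation of fold changes across genes, which are not independent replicates, was 0.50. Both follow from that setting, as unchanged groups give almost no calls and shared controls alone give this correlation. They do not tell how many shared calls the controls add where groups do change. The observed correlations were 0.51, 0.49, 0.01 and 0.10 in the order above, and the covariances were 0.085, 0.162, 0.001 and 0.016 against 0.0090, 0.0090, 0.0090 and 0.0089 simulated. The 3 controls could not be split into parts of at least 2 arrays, so part of the excess over independent lists may come from the shared controls.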

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

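The tests of overall array level, of galactose induction, of a wrong label for IRAK1 replicate 1 and of low control arrays were chosen only after the results they weigh were seen, and the others before.

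Genes that were called against Control in opposite directions by 2 constructs, and whose difference was itself called by limma, were counted as differing between groups. There were 55 such genes between IRAK4 and IRAK4(KD), 19 of them higher and 36 lower in IRAK4. Invertase SUC2, which splits sucrose and raffinose, had the largest difference: it fell in IRAK4 (-1.94 ± 0.11), rose in IRAK4(KD) (1.07 ± 0.11) and differed by -3.01 ± 0.11. Between IRAK1 and IRAK4 there were 230 genes, 131 higher and 99 lower in IRAK1, led by formate dehydrogenase FDH1 (4.64 ± 0.33 and -2.46 ± 0.33, difference 7.10 ± 0.33). Between IRAK2 and IRAK4 there were 157, 83 higher and 74 lower in IRAK2, led by the eisosome protein FMP45 (-0.70 ± 0.16 and 3.03 ± 0.16, difference -3.73 ± 0.16). Between IRAK2 and IRAK1 there were 146, 81 higher and 65 lower in IRAK2. Without IRAK1 replicate 1 the numbers called in opposite directions were 163, 363, 430 and 327 in this order, and with a limit of 2-fold 1, 35, 1 and 1. These counts were not set against those that independent lists would give. They are therefore no measure of how far 2 constructs diverge.

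A signal was also present in the 218 probe sets not paired with exactly 1 gene, which the gene comparisons do not use. Fitted with limma in the same way, 84 were called higher and 26 lower than Control in IRAK4, 28 and 8 in IRAK4(KD), 97 and 46 in IRAK1, and 29 and 10 in IRAK2. Of the 5449 genes, 1539 were called higher and 893 lower in IRAK4, 640 and 327 in IRAK4(KD), 1665 and 1536 in IRAK1, and 317 and 184 in IRAK2. Of the 218 probe sets 19, 0, 36 and 1 were at least 2-fold higher, and their largest rises were 2.28, 0.94, 3.23 and 1.13. What these probe sets measure was not examined. With 3 arrays per group, no statistical test for outlying arrays was made. Fits with 1 array left out and checks of IRAK1 replicate 1 are given below.

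The first pattern weighed is the stress response in IRAK4: 41 of 48 Msn2/Msn4 genes were higher than in IRAK4(KD). A difference in array level is argued against, since all 41 stayed called under median centring, and so is a single deviating or mislabelled array, since at least 39 stayed called with any 1 of the 6 arrays left out. Weaker galactose induction in IRAK4(KD) stays open: the median difference of the galactose list was -0.068, but 1 member was called higher and 1 lower, and GAL1 lies near the top of the range of the arrays. The catalytic activity of IRAK4 may raise these genes, as the design was built to compare, but the level of both proteins was not measured, and a difference in protein level stays open.

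The second pattern is IRAK1 replicate 1, which differed by more than 1 log2 unit from the mean of the other 2 IRAK1 arrays in 234 genes, 62 higher and 172 lower. A wrong label between groups of this series is argued against, since its highest correlation with an array of another group was 0.933 and its lowest with an IRAK1 array 0.968. A different distribution of array values is argued against, since 216 of the genes stayed as far away under quantile normalization. A weaker response of the same kind needs nearly all of these genes to lie toward Control, but 120 of the 234 (51.3%) did. A culture that differed in its growth or a sample from outside the series could give such an array, and no biological explanation was tested.

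The third pattern is the rise of Hsf1 chaperones, called in 29 of 30 genes in IRAK4(KD), 26 in IRAK1 and IRAK2 and 17 in IRAK4, where 6 fell. Low values in the shared controls alone are argued against for IRAK2, since IRAK2 against IRAK4, which uses no control, called 20 genes higher. That test cannot weigh the rise in IRAK4, its reference. A single deviating control is argued against for IRAK2, since at least 24 of the 26 stayed called with any 1 control left out. Both tests were set for IRAK2 and do not cover the rises in the other constructs. For probe sets that may match several transcripts, all 26 genes called in IRAK2 were read by sets without that mark. Only 112 of all 5449 genes are read by marked sets, so this result was likely beforehand and decides little. Reading of similar genes by unmarked sets was not tested. The foreign proteins may load the folding machinery of the cytosol, a hypothesis from these same data that no test here addressed, and protein levels and kinase-specific effects stay open.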

How the results depend on the processing

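The fits without IRAK1 replicate 1 for all groups and the block in 6 arrays were chosen after the data were seen, the other alternatives before. For the 992 named gene results 14515 alternative values were computed. Of these 13874 kept their side of the threshold, 593 lost the call and 48 gained it. The direction reversed in 0 values where either fit called the gene, and a change of direction without a call counted as kept. Most of these results were named for large called changes, which makes a reversal unlikely beforehand. Leaving out 1 array made 514 of the losses. Counts of genes stayed within 1.5 times under median centring, quantile normalization, the filter (4423 genes kept), the mean of probe sets and the trend and robust settings. With a limit of 2-fold, fewer genes by construction, limma called 284 (IRAK4), 86 (IRAK4(KD)), 497 (IRAK1) and 13 (IRAK2) against Control, 188 for IRAK4 against IRAK4(KD), and 332, 368 and 561 for IRAK1 against IRAK4, IRAK2 against IRAK4 and IRAK2 against IRAK1; shared calls became 48 (IRAK4 and IRAK4(KD)), 139 (IRAK4 and IRAK1), 5 (IRAK4 and IRAK2) and 8 (IRAK1 and IRAK2). Array weights, whose estimation stopped before its convergence tolerance and gave IRAK1 replicate 1 a weight of 0.0798, gave 2683 genes for IRAK4(KD), 2591 for IRAK2 and 2890 for IRAK4 against IRAK4(KD). The 6 arrays of the groups compared gave 1728 for IRAK4(KD), 1407 for IRAK2 and 1486 for IRAK1 against IRAK4. Without IRAK1 replicate 1 in the shared spread the counts were 1857 for IRAK4(KD) and 1180 for IRAK2, and shared calls 1072 (IRAK4 and IRAK4(KD)), 322 (IRAK4 and IRAK2) and 485 (IRAK1 and IRAK2), with 163, 430 and 327 genes in opposite directions (363 for IRAK4 and IRAK1). Leaving out this array changes no group mean but that of IRAK1. In comparisons without IRAK1 the added calls therefore come from the changed estimate of the spread alone. With 1 array left out, counts ranged from 325 to 907 for IRAK4(KD) and from 146 to 405 for IRAK2, with fewer arrays. With an estimated correlation camera called 0 lists for IRAK4 (18 with the preset), 1 for IRAK4(KD) (17), 1 for IRAK1 (19), 1 for IRAK2 (19) and 0 for IRAK4 against IRAK4(KD) (12). At an unadjusted p under 0.05 these were 6, 6, 8, 5 and 4. How far the lost calls rest on IRAK1 replicate 1, which entered every estimate, was not tested. The replicate block gave 2345 genes for IRAK4, 861 for IRAK4(KD), 3157 for IRAK1, 435 for IRAK2 and 1823 for IRAK4 against IRAK4(KD), and 2462, 2732 and 3183 for the other comparisons; it moved no count over 1.5 times, and the numbers of lists called stayed at 18, 17, 19, 19 and 12. In the 7 comparisons other than IRAK1 against Control at least 1 same-numbered pair correlated under 0.1. Weak signal could not be told from background, since no detection calls were used.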

Other observations

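The zinc test was chosen after its genes were seen, and its bound was revised after its value was known; the splits were chosen before.

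The cyclin genes CLN2 and PCL1 differed between IRAK1 and IRAK4. CLN2, which drives entry into the cell cycle, rose in IRAK4 (1.21 ± 0.12) and fell in IRAK1 (-1.40 ± 0.12) and IRAK2 (-0.52 ± 0.12), where the call ended without IRAK2 replicate 2 (-0.43) or 3 (-0.53). PCL1, a cyclin of the kinase Pho85, rose in IRAK4 (1.22 ± 0.08), and the difference of IRAK1 from IRAK4 was -2.13 ± 0.08 (-2.61 ± 0.12 for CLN2). In IRAK4(KD) CLN2 was not called (-0.02 ± 0.12), and IRAK4 was 1.23 ± 0.12 higher than IRAK4(KD). Of 35 G1/S genes 13 rose and 3 fell in IRAK4, also when adjusted over the list alone, and 1 fell with any 1 Control array or IRAK4 replicate 3 left out (camera, adjusted p = 0.0383; adjusted p = 0.44 with an estimated correlation).

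The plasmid and mating type genes gave further values. URA3 differed from Control by 0.06 in IRAK4, 0.10 in IRAK4(KD) and 0.05 in IRAK2, none called, and fell in IRAK1 (-0.20 ± 0.08). That call ended without Control replicate 1 (-0.16), Control replicate 2 (-0.21) or IRAK1 replicate 2 (-0.17) and in a fit of the 6 arrays alone (-0.20). With array weights URA3 was called in IRAK4(KD) (0.14). LEU2 fell in IRAK1 (-0.44 ± 0.10) and was not called in the others. It was called in IRAK4 (-0.23) without IRAK4 replicate 2 (-0.31), with median centring (-0.30) and with array weights (-0.18), and in IRAK4(KD) and IRAK2 with array weights (-0.18 in both). Of 5 genes specific to cells of the other mating type 2 rose in IRAK4 (3 adjusted over the list alone), 1 in IRAK4(KD), 1 in IRAK1 and 0 in IRAK2, and camera called the list in none (adjusted p = 0.23, 0.33, 0.77 and 0.74).

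In IRAK4(KD) a rise of the zinc regulon as a whole could stand behind ZPS1, ADH4, VEL1 and YOR387C, but only 3 of 16 zinc genes were called higher and the median was 0.31 (7 higher and 1 lower without IRAK1 replicate 1); ZRT1, a zinc transporter chosen after its value was seen, was at 0.22 ± 0.10. The test leaves this open.

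Each comparison of 3 arrays with 3 has 10 splits of its arrays, so a share under 0.05 cannot be reached. With limma on the 6 arrays, the real split called 2786 genes for IRAK4, 1728 for IRAK4(KD), 2455 for IRAK1 and 1407 for IRAK2 against Control, 2186 for IRAK4 against IRAK4(KD), 1486 for IRAK1 against IRAK4, 3177 for IRAK2 against IRAK4 and 2549 for IRAK2 against IRAK1. The highest other split called 0 in each, and 133, 493, 171, 230, 326, 227, 51 and 114 at an unadjusted p under 0.05, so 1 split of 10 was as large as the real one, the real one itself. Camera called 18, 17, 19, 19 and 14 lists in the real splits of the first 5 comparisons and at most 16, 19, 21, 15 and 16 in the others, and 1, 2, 4, 1 and 2 splits were as large. For IRAK1 and Control 4 splits part all 3 pairs; the highest of the others among them called 0 genes and 21 lists, and splits that part fewer pairs called at most 0 and 21. Each other split sets 2 arrays of a group and 1 of the other against the rest, so it keeps part of the real difference. The splits therefore cannot tell how many lists camera calls where groups do not differ. For IRAK4(KD) and IRAK1 against Control and for IRAK4 against IRAK4(KD), another split called as many lists or more. There the number of lists called did not set the real split apart.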
